A study of Homo sapiens with 12 samples.

How the data were processed

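Total RNA from 12 samples of HK-2 cells was hybridised to Affymetrix 3′ expression arrays, 3 samples for each of 4 groups: Ra and control at 12 h and at 48 h. Group, time and replicate number were taken from the labels. Per the submitters' processing notes, the authors made the deposited values with GCRMA, which corrects the background by probe sequence, normalizes arrays against each other and summarises each probe set. The deposited values are on a log2 scale, as their range on each array shows. The version of GCRMA, the set of arrays normalized together and any further filter are not given in the sources used here, and detection calls were not used here. GCRMA shrinks low signals, so a fold change that involves a group under about 5 log2 units depends on the background model. The spread between replicates in such a group, and with it any test, depends on that model too. No 2 arrays held identical values (0 pairs).

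Genes were named through the platform annotation: 41097 probe sets had 1 gene symbol, 1801 had several and 11777 were unnamed there. Entrez numbers of 41043 matched the current RefSeq list, which changed 0 symbols. Probe sets with 1 symbol were kept where at least 3 arrays reached 5 log2 units (17339 probe sets), and the probe set with the highest mean over all 12 arrays stood for its gene, giving 10050 genes. Other probe sets of some named genes gave the opposite sign, as for IFIT2 and PAX8 at 48 h, where the differences are small or do not pass, and others differed in size by over 1.5-fold, as for NT5E and MCM10 at 48 h.

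Linear models were fitted with limma 3.58.1 in R 4.3.3: a mean for each of the 4 groups over all 12 arrays (8 residual degrees of freedom), moderated with an intensity trend, and Benjamini-Hochberg adjustment over the 10050 genes at 0.05. The contrasts were Ra against control at each time, the difference of these effects, and control 48 h against control 12 h. Of 32 gene lists fixed before the data were examined, 30 with at least 4 measured members were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation, and with fry, which tests whether a list moves one way. The lists for aryl hydrocarbon receptor targets (3 measured members) and retinoid response (2) were too small. Genes named in the text are, at each time, the 10 largest rises and 10 largest falls among those past the test, changed at least 2-fold and with no overlap between the groups' arrays, up to 5 each way for the difference between the times, up to 4 members of each called list with the largest change, and GAPDH and ACTB. That rule was fixed before the data were examined. Its use on the fit of the 6 arrays of 12 h was added after the data were seen.

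The replicate numbers were checked as pairs by correlating the deviations of same-numbered arrays from their group means. At 12 h all 3 correlations between Ra and control arrays exceeded 0.1 (0.182, 0.421 and 0.344), so the numbers may pair those samples. Differently numbered arrays were not compared, so a pairing is not shown. At 48 h the correlations were 0.301, -0.219 and 0.097, which gives no sign of pairs.

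The code was tested on simulated data with changes of 0.5, 1 and 2 log2 units in 67, 67 and 66 of the 10050 genes. With 1 spread for all groups, the 12-array test recovered 2.99%, 35.8% and 81.8% of the 3 sizes at 12 h and 5.97%, 29.9% and 90.9% at 48 h. The 6-array test of 12 h recovered 38.8%, 82.1% and 98.5% of the 3 sizes, with 3 false calls of 149. With each time's own spread, the 12-array test at 48 h made 126 false calls of 239.

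Alternatives were other filters (none, or 7 log2 units), the mean of a gene's probe sets, leaving out cross-hybridising probe set types, quantile normalization, centring of arrays, moderation without the intensity trend or with robust variance, array weights, the replicate number as a block, a 2-fold minimum, fits on 6 arrays and leaving out each array in turn. Plots were drawn with matplotlib.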

Results

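HK-2 cells, an immortalised line from the human kidney's proximal tubule, were exposed to a compound called Ra or to its vehicle for 12 h or 48 h, in a series that looks for expression signatures of kidney toxicity. Total RNA of 12 samples, 3 per group, was measured on Affymetrix 3′ expression arrays. The labels call the 3 samples of each group biological replicates. What Ra is and its dose were not given in the sources used here. Values are GCRMA log2 expression values, and the number of arrays, not a count depth, limits the precision. Probe sets with exactly 1 gene symbol and enough signal gave 10050 tested genes.

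The 12 h arrays were closely alike, with correlations of 0.997 to 0.998 within each group. The 48 h arrays varied more. The median gene's SD between replicates was 0.12 log2 units in both 12 h groups, 0.22 in control cells at 48 h and 0.43 in Ra-treated cells at 48 h. Ra 48 h replicate 2 stood apart: the SD over its probe sets was 2.81, against 3.09 to 3.14 on the other 11 arrays, and its 75th percentile was 6.30, against 7.01 to 7.21. Over both 48 h groups together the median gene's SD was 0.37, and 0.23 without that array, against 0.14 over both 12 h groups. The 3′ minus 5′ signal of the ACTB control probe sets, a measure of RNA integrity, was 0.95 ± 0.17 log2 units with Ra and 1.07 ± 0.15 in control cells at 48 h (SD, n = 3; two-sided exact permutation p = 0.4). At 12 h it was 0.94 ± 0.05 with Ra and 0.91 ± 0.10 in control cells (exact permutation p = 0.8). With 3 arrays against 3 such a test cannot go below 0.1. GAPDH and ACTB themselves gave log2 differences of 0.05 ± 0.08 and -0.07 ± 0.09 at 12 h and of -0.04 ± 0.08 and 0.07 ± 0.09 at 48 h (SE). Of the markers fixed for other cell types, 3 of 9 fibroblast genes, 1 of 10 endothelial genes and 3 of 6 podocyte genes were measured above the filter. Of the immune genes and of those of the distal nephron and collecting duct, 0 of 9 each were measured. Of the measured markers 0 passed limma's test with Ra at 12 h, where 3 of all 10050 genes passed, or at 48 h, where 12.6% did. With so few calls at 12 h that result was nearly fixed in advance.

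The first comparison asked what Ra did within 12 h. Genes for making ribosomes had lower means in the treated cells (median of 25 genes -0.50 log2 units), and interferon-stimulated genes had higher means (median of 21 genes 0.79). In limma's fit of all 12 arrays, 3 genes passed an adjusted p of 0.05, all higher with Ra. KLHL24, which encodes an adaptor of a ubiquitin ligase, rose by 2.15 ± 0.31 log2 units (SE, n = 3 per group; 4.44-fold), UBALD2 by 1.75 ± 0.24 and EVC, a protein of the primary cilium, by 1.38 ± 0.20, each with a limma adjusted p of 0.0493. Other probe sets of KLHL24 gave 1.97, 2.25 and, for one of a type that can cross-hybridise, 0.05. At an unadjusted p under 0.05 there were 751 genes, where 502.5 would be given by chance, and the groups did not overlap for 35.3% of genes (chance 10%).

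That fit shares 1 spread estimate with the more variable 48 h arrays. Fitted on the 6 arrays of 12 h alone, an alternative fixed before the data were examined, limma called 1366 genes, of which 738 rose and 628 fell. At least 2-fold changes were fewer, with 74 rises and 15 falls. SLC16A14, a member of the monocarboxylate transporter family, rose from 2.57, at background in control cells, to 5.49. Its difference of 2.92 ± 0.33 log2 units (SE) therefore depends on GCRMA's background model, as do those of CRACD, YPEL1, ZMAT1 and SLITRK4, which have a group under 5. IFIT2, an interferon-induced gene, rose by 2.13 ± 0.45, CREBRF, a regulator of the CREB3 family, by 2.13 ± 0.23, and CRACD by 1.98 ± 0.32. ANKRA2 rose by 1.80 ± 0.14, YPEL1 by 1.79 ± 0.15, ZMAT1 by 1.72 ± 0.22 and NATD1 by 1.69 ± 0.28. The largest falls were those of RHEX (-1.74 ± 0.36), CCBE1 (-1.42 ± 0.24), ZBED2 (-1.41 ± 0.18) and the D-type cyclin CCND2 (-1.37 ± 0.15). Falls were also called for SLITRK4 (-1.35 ± 0.33), the small GTPase RRAD (-1.31 ± 0.15), SCFD2 (-1.24 ± 0.19), RAB20 (-1.22 ± 0.19), RASSF4 (-1.21 ± 0.17) and TENT5B (-1.16 ± 0.17). With KLHL24 and UBALD2 these are the 20 genes that the naming rule gives in this fit, with limma adjusted p between 0.00395 for UBALD2, ANKRA2 and YPEL1 and 0.0354 for SLITRK4. Other probe sets of CREBRF gave 1.57 and 0.83.

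All 25 measured ribosome biogenesis genes had lower means with Ra at 12 h, with a median of -0.50 log2 units. In the fit of 12 arrays 0 of them passed over all genes and 7 fell adjusted over the list alone. In the 6-array fit 16 fell, among them NOP16 (-1.01 ± 0.08, SE), DDX10 (-0.85 ± 0.15), LYAR (-0.79 ± 0.12) and NOP2 (-0.70 ± 0.08). Of 21 interferon-stimulated genes 20 had higher means, with a median of 0.79. Here 0 passed over all genes in the fit of 12 arrays, 8 rose adjusted over the list alone, and 8 rose in the 6-array fit, with IFI44L at 1.60 ± 0.35, IFI44 at 1.59 ± 0.36 and DDX60 at 1.38 ± 0.29. Limma's camera with a preset correlation called both lists (adjusted p = 2.35e-15 and 2.09e-10), and both calls were lost, at an adjusted p = 0.772 with an estimated correlation. In the 6-array fit the estimated correlation gave adjusted p = 0.174 for ribosome biogenesis and 0.518 for interferon-stimulated genes. There fry, which tests whether a list moves one way, called ribosome biogenesis (adjusted p = 0.00302) and not the interferon list (0.119).

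Smaller shifts were called by camera for another 10 lists at 12 h, at an adjusted p = 0.872 for each with an estimated correlation. In the fit of 12 arrays 0 members of these lists passed over all genes. Adjusted over the list alone, 3 autophagy and lysosome genes, 1 NRF2 target and 1 hypoxia gene passed, and 0 in the other lists. Heat shock genes had a median of -0.24, and 7 of 19 fell in the 6-array fit, including FKBP4 (-0.64 ± 0.09) and HSPA4 (-0.45 ± 0.06). Proteasome genes had a median of -0.15, and 4 of 28 fell in that fit, PSMB5 by -0.34 ± 0.09 and PSMD12 by -0.33 ± 0.09 among them. Of 40 nuclear genes of oxidative phosphorylation (median -0.13), 5 fell, including ATP5MC1 (-0.62 ± 0.14) and CYCS (-0.42 ± 0.05). Of 19 autophagy and lysosome genes (median 0.21), 7 rose and 1 fell; GABARAPL1, whose product is built into autophagosomes, rose by 0.91 ± 0.11 and SQSTM1 by 0.65 ± 0.13. The immediate early and ERK list (median 0.25) had 6 of 19 members that rose, PHLDA1 by 0.85 ± 0.11 and ETV4 by 0.71 ± 0.14. The lists for NRF2 targets (median 0.18), hypoxia (0.23), TGF-beta response (0.14) and epithelial junctions (0.13) were shifted upwards by camera. In the 6-array fit 4 of 24 NRF2 targets rose and 1 fell, 5 of 18 hypoxia genes rose and 1, EGLN3, fell (-0.85 ± 0.20), and 2 of 18 TGF-beta and 2 of 16 junction genes rose. Among the rises were ABCC3 (0.93 ± 0.10), BNIP3L (0.67 ± 0.06), SMAD7 (0.77 ± 0.12) and JUP (0.58 ± 0.11). Of 29 fixed proximal tubule genes only 8 were measured above the filter, with a median of -0.12, and 3 of the 8 had higher means. In the 6-array fit 3 fell, SLC22A5 by -0.76 ± 0.15, PAX8 by -0.46 ± 0.09 and ABCB1 by -0.44 ± 0.07. Camera did not call the proximal tubule list in that fit (adjusted p = 0.0729). The calls for TGF-beta response, epithelial junctions and proximal tubule genes were lost after centring each array on its median (adjusted p = 0.112, 0.0689 and 0.101), with their direction kept. In the 6-array fit fry called heat shock (adjusted p = 0.0305), the ERK list (0.0364) and epithelial junctions (0.0108), while the adjusted p with an estimated correlation was 0.397, 0.397 and 0.454.

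Same-numbered samples deviated together at 12 h. With the replicate number as a block the 6-array fit called 2351 genes, and with the number as a block within each time the fit of 12 arrays called 0 in place of 3. Of the 24 list calls by camera at 12 h and 48 h, 5 were lost with the block in the fit of 12 arrays. With the block within each time 1 was lost. The call of 3 genes became 0 without any 1 of the 6 arrays of 12 h or without control 48 h replicate 2, 1 without control 48 h replicate 1, and 219 without Ra 48 h replicate 2. The 1366 genes became 332 without Ra replicate 1, 293 without Ra replicate 2, and 412, 527 and 584 without control replicates 1, 2 and 3.

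**Figure D1:**
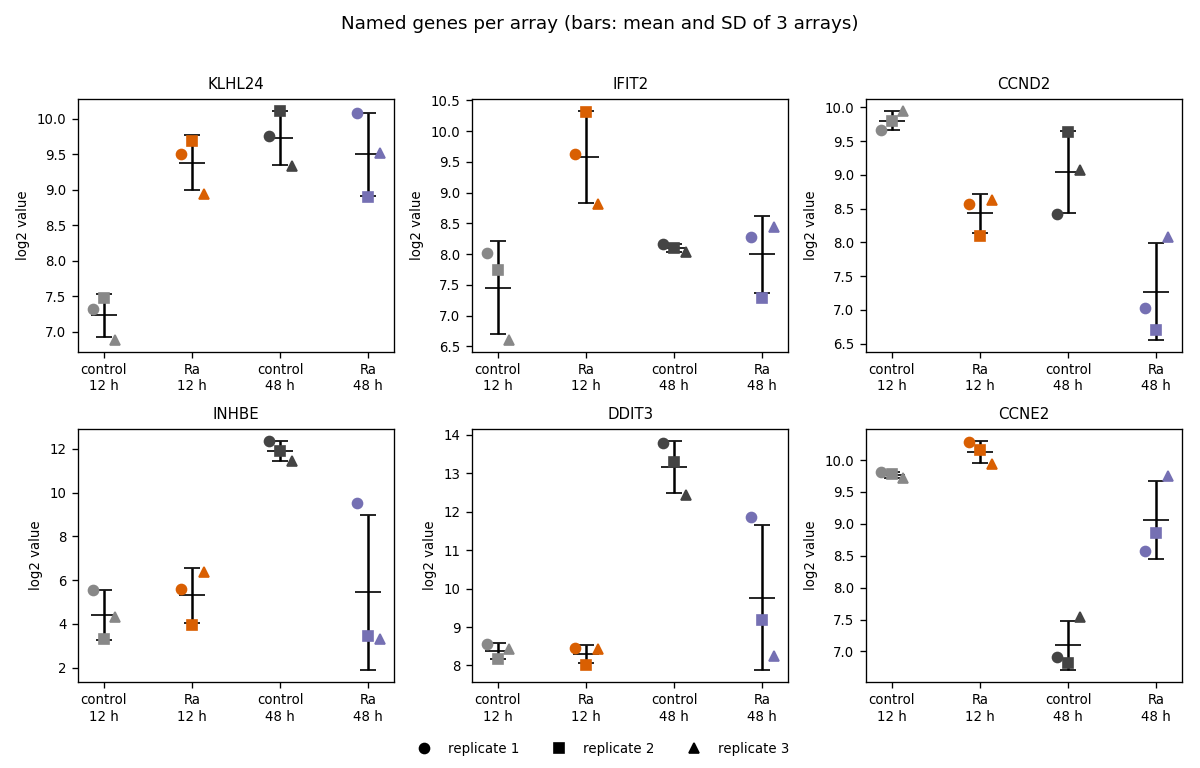
Log2 expression values of 6 named genes on each of the 12 arrays, by group, with marker shapes for replicate numbers and bars for the mean and SD of 3 arrays. INHBE and DDIT3 lie highest in the control cells at 48 h (means 11.90 and 13.17), and KLHL24 lies at 7.23 in control cells at 12 h and above 9 in the other groups.

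The second comparison asked what differed after 48 h. Of 34 genes of the ATF4 and amino acid response 32 fell with Ra against control cells of the same time. Of 23 genes for endoplasmic reticulum chaperones and the unfolded protein response, together called the chaperone list, 8 fell. Of the genes of DNA replication 22 of 38 rose, and of those of G2 and mitosis 9 of 34. The arrays' mean levels of the chaperone and mitosis lists overlapped between the groups (two-sided exact permutation p = 0.2 for each), and those of the ATF4 and replication lists did not (exact p = 0.1, the smallest possible). In limma's fit of all 12 arrays 1262 genes changed, with 301 higher and 961 lower in Ra-treated cells, and 675 of them by at least 2-fold. The groups did not overlap for 24.0% of genes (chance 10%), against 35.3% at 12 h. The median of all genes was shifted by -0.20 log2 units, and without Ra 48 h replicate 2 by 0.01, with 1126 genes higher and 817 lower. After quantile normalization the count was 3014 with 1553 higher and 1461 lower, and after centring each array on its median 2863 with 1578 higher and 1285 lower, scalings that bring all arrays to a common level. The surplus of falls did not hold without Ra 48 h replicate 2.

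INHBE, an inhibin subunit gene induced by stress signalling, fell by 6.46 ± 1.30 log2 units (SE, n = 3 per group), from 11.90 to 5.44. CTH, which makes cysteine from cystathionine, changed by -4.10 ± 0.91, ANK2 by -4.00 ± 0.64, ALDH1L2, a mitochondrial folate enzyme, by -3.98 ± 0.65, and the cystine transporter SLC7A11 by -3.67 ± 0.84. The stress-induced transcription factors ATF3 and DDIT3 changed by -3.52 ± 0.57 and -3.41 ± 0.68, CAMTA2 by -3.42 ± 0.64, the unfolded protein sensor ERN1 by -3.40 ± 0.72 and CLIP4 by -3.38 ± 0.31. The adjusted p of these 10 genes lay between 0.000822 for CLIP4 and 0.022 for SLC7A11 in limma's fit. With Ra, ANK2, ALDH1L2 and CLIP4 lay under 5 (4.79, 4.44 and 2.70), so the size and the adjusted p of their falls depend on the background model. CLIP4 had the smallest SE of the 10 genes (0.31) as well as the lowest adjusted p. The highest rises by the probe set chosen for each gene were SHISA2 (2.52 ± 0.64), LYPD1 (2.34 ± 0.42), the histone chaperone ASF1B (2.07 ± 0.33), the nucleotidase NT5E (2.06 ± 0.40), and CTHRC1 (2.06 ± 0.40). Rises were also called for cyclin E2 (CCNE2, 1.96 ± 0.28), the replication factor MCM10 (1.95 ± 0.39), the tight junction gene CLDN2 (1.91 ± 0.52), FOSL1 (1.91 ± 0.42) and TM4SF1 (1.90 ± 0.50), with adjusted p between 0.00828 for CCNE2 and 0.0364 for CLDN2. Other probe sets gave 0.70 and 0.92 for NT5E, 0.99 and 0.96 for MCM10, and -4.38 for ATF3.

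By list, 32 of 34 ATF4 and amino acid response genes fell, and 32 adjusted over the list alone, with a median of -1.93. Of the 23 genes for endoplasmic reticulum chaperones and the unfolded protein response 8 fell, and 22 adjusted over the list alone. The median of that list was -1.29, with HERPUD1 at -2.49 ± 0.61, DNAJB9 at -2.22 ± 0.65 and SEC24D at -1.83 ± 0.47. Of 38 DNA replication genes 22 rose, 28 adjusted over the list alone (where 1 fell), with a median of 0.89, among them the cyclin CCNE1 (1.64 ± 0.32), while CDC6 had a difference of -1.51 ± 0.51 that did not pass. Of 34 G2 and mitosis genes 9 rose, 21 adjusted over the list alone, with a median of 0.74, including KIF20A (1.23 ± 0.27), CCNA2 (1.15 ± 0.31) and PTTG1 (1.14 ± 0.25). The camera calls of these 4 lists (adjusted p from 5.25e-22 for DNA replication to 2.52e-06 for the chaperones) were lost with an estimated correlation, at adjusted p = 0.996 with an estimated correlation for the chaperones and 0.915 for the other lists. Fry called 0 lists at 48 h, with its lowest adjusted p, 0.0516, for the ATF4 list.

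Camera called 8 more lists at 48 h, each at adjusted p = 0.996 with an estimated correlation. The arrays' mean levels of all 8 lists overlapped between the groups (two-sided exact permutation p from 0.2 to 0.8). Control 48 h replicate 3 lay nearer to the Ra arrays than the other control arrays did for metallothioneins (-0.16 against -1.20 and -1.26, relative to control cells at 12 h) and for tubulins (-0.47 against -1.54 and -0.97), as it did for the mitosis and chaperone lists. Metallothioneins had a median of 0.71, with 0 of 8 past the test over all genes and 6 that rose adjusted over the list alone; MT1X stood at 0.93 ± 0.29. Tubulins had a median of 0.53, and TUBB4B (0.82 ± 0.20) and TUBB (0.73 ± 0.20) rose. In the immediate early and ERK list (median 0.37) 4 of 19 rose, including CCND1 (1.35 ± 0.38, and 0.77 by its other probe set) and SPRY2 (1.13 ± 0.32). Of the SRF and YAP list (median 0.26), TPM1 rose by 0.61 ± 0.18 and AJUBA changed by -0.91 ± 0.21. Of 19 cholesterol genes (median -0.63) 2 fell, HSD17B7 (-1.46 ± 0.30) and STARD4 (-1.32 ± 0.39). The 3 Ra arrays differed widely: relative to control cells at 12 h their mean levels ran from -1.34 to -0.48 for this list. They ran from -1.08 to -0.36 for ribosome biogenesis, from -0.23 to 0.55 for autophagy and lysosome and from -0.60 to 0.48 for the ERK list. The calls for ribosome biogenesis (median -0.42; 4 of 25 fell, NOP16 by -0.93 ± 0.26), autophagy and lysosome (median -0.37; 6 of 19 fell, WIPI1 by -1.46 ± 0.40 and MAP1LC3B by -0.85 ± 0.16) and TGF-beta response (median 0.19; LTBP2 rose by 1.31 ± 0.27) were lost after centring each array on its median (adjusted p = 0.123, 0.071 and 0.0828). Adjusted over the list alone, 6 tubulins, 5 ERK list genes and 1 SRF and YAP gene rose. On that basis 1 SRF and YAP gene, 7 cholesterol genes, 7 ribosome biogenesis genes and 10 autophagy and lysosome genes fell, and 3 TGF-beta genes rose and 2 fell. Without Ra 48 h replicate 3 the median of the TGF-beta list was -0.02.

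These calls at 48 h, and the SEs given with them, rest on the 12 h arrays for their spread. Fitted on the 6 arrays of 48 h alone, limma called 0 genes (lowest adjusted p = 0.168, 1748 genes at an unadjusted p under 0.05). On simulated data that fit recovered 1.49%, 4.48% and 54.5% of changes of 0.5, 1 and 2 log2 units. In data simulated with each time's own spread 126 of 239 calls of the 12-array test were false (52.7%). There only 67, 67 and 66 of the 10050 genes were changed, by those sizes, and genes varied independently. The false share depends on that number, so it does not estimate the share among the 1262 calls. In 1000 simulations with no effect of Ra, in which each group kept its own residuals, 140 gave at least 1262 calls at 48 h (median 0). The count of 1262 became 45 without control 48 h replicate 2, 118 without control 48 h replicate 1, and 1982 without control 48 h replicate 3. It became 2725, 1943 and 612 without Ra 48 h replicates 1, 2 and 3, and 692 to 757 without any 1 of the 12 h arrays.

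**Figure D2:**
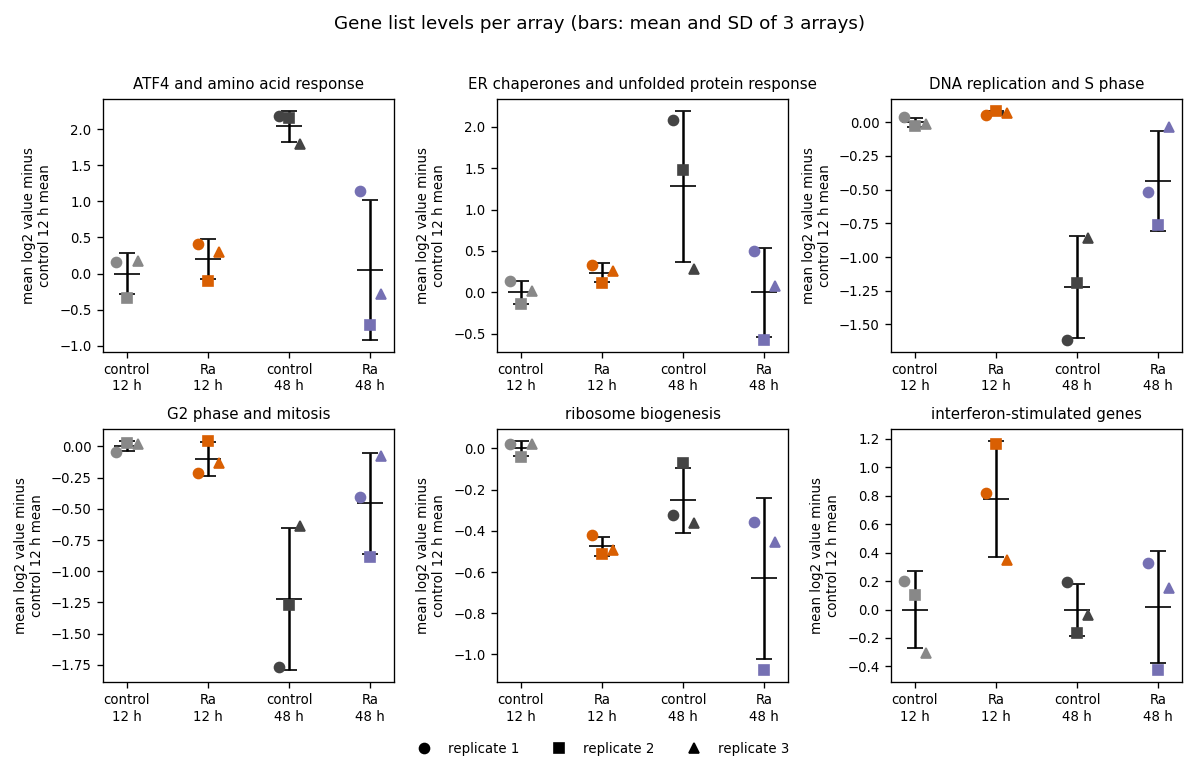
Mean log2 value of the measured members of 6 gene lists on each array, minus the mean of the control arrays at 12 h, by group, with marker shapes for replicate numbers and bars for the mean and SD of 3 arrays. The ATF4 list lies at 2.04 in control cells at 48 h and at 0.05 in Ra-treated cells at 48 h, where the 3 arrays spread from -0.71 to 1.14.

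The third comparison asked whether the effect of Ra differed between the times. C5AR1, a complement receptor gene, differed by -4.13 ± 0.44 log2 units between the effect at 48 h and that at 12 h (limma adjusted p = 0.00523). It stood at 3.29 in control and 4.78 in Ra-treated cells at 12 h and at 6.11 and 3.47 at 48 h. CLIP4 differed by -3.38 ± 0.43 (adjusted p = 0.0183), with means of 2.69, 2.70, 6.07 and 2.70 in the same order. Values under 5 depend on GCRMA's background model, and so do the spread and the adjusted p taken from them. CLIP4 lost its call without any 1 of the 12 h arrays, without Ra 48 h replicate 3 and without control 48 h replicate 2 (adjusted p from 0.0531 to 0.0914), and C5AR1 kept its call without each array in turn. These were the 2 genes called of 10050, with 1933 at an unadjusted p under 0.05. The count became 60 with the replicate number as a block and 36 with the number as a block within each time. It became 1041 without Ra 48 h replicate 1, 320 without Ra 48 h replicate 2, 572 without control 48 h replicate 3, and 1 without Ra 48 h replicate 3 or without any 1 of the 12 h arrays.

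Of the genes called at either time in the fit of 12 arrays, 1 was shared in the same direction, UBALD2. It rose by 1.75 ± 0.24 at 12 h and 1.02 ± 0.24 at 48 h, with equal SEs because that fit pools the spread over all 12 arrays. That count of 1, where independent lists would give 0.0899, became 45 without Ra 48 h replicate 2, and 0 without any 1 of the 12 h arrays, without Ra 48 h replicate 3 or without control 48 h replicate 1 or 2. Between the 12 h calls of the 6-array fit and the 48 h calls, 141 genes were shared in the same direction, where independent lists would give 82.2, and 57 in opposite directions, where they would give 89.4. Among them CCND2 fell at both times (-1.78 ± 0.35 at 48 h), as did SLITRK4 (-2.17 ± 0.43 at 48 h), and ABCC3, IFI44L and YPEL1 rose at both (1.37 ± 0.20, 1.72 ± 0.46 and 1.26 ± 0.34 at 48 h). Across the 10050 genes, which are not independent replicates, the log2 changes at both times had a Pearson r of 0.084 and a Spearman rho of 0.098.

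The control cells themselves changed between 12 h and 48 h. The stress genes ATF3 and DDIT3 rose by 5.44 ± 0.57 and 4.79 ± 0.68 log2 units, INHBE by 7.51 ± 1.30 and SLC7A11 by 3.86 ± 0.84. The replication gene MCM10 changed by -3.31 ± 0.39 and CCNE2 by -2.67 ± 0.28 (SE, n = 3 per group). In limma's fit of 12 arrays 1955 genes changed, 942 higher and 1013 lower at 48 h. Of the ATF4 list 30 of 34 rose (34 adjusted over the list alone; median 1.60), and of the autophagy and lysosome list 10 of 19 rose and 1 fell (14 and 1 adjusted over the list alone; median 0.71). Of the DNA replication list 34 of 38 fell (34 adjusted over the list alone; median -1.17), of the G2 and mitosis list 32 of 34 (33 adjusted over the list alone; median -1.18), and of 10 tubulins 8 (9 adjusted over the list alone; median -0.91). Camera called 15 lists, and the adjusted p of each was 0.811 or higher with an estimated correlation. Fry called 5 lists: DNA replication (adjusted p = 0.0167), ATF4 (0.0271), G2 and mitosis (0.0285), tubulins (0.0309) and autophagy and lysosome (0.0316). The count of 1955 genes became 3334 on the 6 control arrays alone, 4095 without Ra 48 h replicate 2, 828 and 864 without control 48 h replicates 1 and 2, and 1028, 899 and 788 without control 12 h replicates 1, 2 and 3.

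Ra-treated cells at 48 h lay between the 2 control groups for 1513 of those 1955 genes (77.4%). In 1000 simulations with no effect of Ra the share was 56.2% on average, with a central 95% range from 15.8% to 92.7%. Of the 660 genes called both with time in control cells and with Ra at 48 h, 659 moved in opposite directions (99.8%). In the same simulations 139 of 1000 had at least 660 genes called in both, and the share in opposite directions, in the 234 with any, was 60.7% on average with a central 95% range from 0% to 100%. The number called in both became 1175, 1375 and 290 without Ra 48 h replicates 1, 2 and 3 and 80, 32 and 1234 without control 48 h replicates 1, 2 and 3. Both comparisons use the control arrays of 48 h, so their log2 changes are negatively related with no effect of Ra at all. The covariance across genes was -0.303, against a mean of -0.042 in 1000 simulations with no effect of Ra and a central 95% range from -0.291 to 0.124.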

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

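The tests of Ra 48 h replicate 2 as the whole cause of the low 12 h count, of its 3′ minus 5′ signals, and of that array and the scaling as the source of the opposite movement were chosen after the result was seen. The rule for reading the shared control arrays was also made stricter after its result was seen.

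The effect of Ra differed between the times by limma's test of the difference for C5AR1 (-4.13 log2 units, effect at 48 h minus effect at 12 h) and CLIP4 (-3.38). Of the 4 group means 3 lie under 5 log2 units for each, so the sizes and the adjusted p depend on GCRMA's background model. Camera, with a preset correlation, called a difference for 15 lists, at adjusted p from 1.10e-19 to 0.0445. With an estimated correlation 0 of the 15 calls held (lowest adjusted p = 0.810; 0 of 30 lists at an unadjusted p under 0.05), and fry called 0 (lowest adjusted p = 0.232). The median difference was -1.99 for the ATF4 and amino acid response and -1.63 for the list of endoplasmic reticulum chaperones and the unfolded protein response. It was -0.87 for hypoxia, -0.78 for interferon-stimulated genes, -0.59 for autophagy and lysosome, -0.52 for epithelial junctions and -0.48 for NRF2 targets. It was 0.011 for oxidative phosphorylation, 0.10 for ribosome biogenesis, 0.14 for heat shock, 0.29 for SRF and YAP targets, 0.50 for metallothioneins, 0.62 for tubulins, 0.79 for DNA replication and 0.87 for G2 and mitosis. The median of all genes was itself -0.19, and 0.02 without Ra 48 h replicate 2. Of 100 splits of the samples, 5 gave as many genes as the real one (2 genes, highest other 6) and 16 gave as many lists (15 lists, highest other 20), so chance is not excluded for either count. Among the 44 of these splits that part the pairs of 12 h, 2 gave as many genes and 8 as many lists, the real split included. For genes that share is under 0.05, so the reading of the gene count depends on the pairing, which is not shown. With the replicate block within each time, 2 of the 32 splits that part all pairs at both times gave at least the real 36 genes. The other one gave 305, and the reason was not tested.

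Of the 1262 genes called at 48 h, 660 were also called with time in control cells, and 659 of these moved opposite to that change. This share was 97.7% or higher without each array of 48 h and after quantile normalization, so it cannot tell the explanations below apart. Over the 3334 genes called on the 6 control arrays alone, Ra-treated cells went back by a median of 60.2% of the control change, where simulations with no effect of Ra gave 5.93% on average (central 95% range from -24.2% to 34.3%). Against Ra 48 h replicate 2 as the source stands that this was 59.4% without it (38.2% and 81.1% for the other Ra arrays singly), and against the scaling of the arrays that it was 60.6% after quantile normalization (38.9% to 81.1% singly). The control arrays of 48 h, shared by both comparisons, were not told apart from an effect of Ra. The percent gone back lay above its simulated range, with 0 of 998 simulations as high. But the simulations took the observed control change as the true one. That change holds the noise of the same arrays, so the simulated ranges may be too narrow. The covariance of -0.303 lay just below the simulated range from -0.291 to 0.124 (19 of 1000 simulations as low). That bound was set before the result was seen. The covariance passed it by less than its spread: without 1 array of 48 h it ran from -0.455 to -0.233. The correlation of -0.736 lay inside its own simulated range from -0.804 to 0.613 (67 of 1000 as low). A treatment effect, with less of the change over time in Ra-treated cells, stays open.

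At 12 h the fit of 12 arrays called 3 genes and the fit of 6 arrays 1366. Against Ra 48 h replicate 2 as the whole cause stands that without it the count was 219. Both fits give the same log2 differences at 12 h, so their counts differ through the spread estimate and its degrees of freedom. The wider spread of the 48 h arrays is a candidate explanation. With their residuals shrunk by a factor of 0.369, to the spread of the 12 h arrays, the fit of 12 arrays called 1789 genes, 1012 higher and 777 lower. Shrinking lowers the pooled spread by construction, so a rise of the count was fixed in advance. No biological explanation was tested.

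Ra 48 h replicate 2 stood apart from the other Ra arrays of 48 h, with a median distance 2.88 times theirs to each other. RNA degradation stays open: its 3′ minus 5′ signals, 1.13 for ACTB and -0.01 for GAPDH, lay within the ranges of the other 11 arrays (0.79 to 1.19 and -0.11 to 0.03), but that of ACTB lay above the other Ra arrays of 48 h (0.795 and 0.910). A narrower scale of its values may explain most of the distance, since the ratio was 1.20 after quantile normalization. Why its scale was narrower was not tested. GCRMA normalizes arrays against each other, but the set normalized together is not given, so the processing and a difference between cultures both stay open.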

How the results depend on the processing

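The replicate block within each time, the 6 arrays of 12 h as a result of their own, the 48 h arrays without Ra 48 h replicate 2, the overlap with 12 h calls from 6 arrays and the lists in fits of 6 arrays were chosen after seeing the data. The cause was not tested for the changes below, except that the spread of the 48 h arrays acts on the pooled fit and a 2-fold minimum can only lower a count. At 12 h the 3 genes became 1 with no filter, 5 with a stricter filter, 1 with the mean of probe sets, 153 after quantile normalization, and 119 after centring. They became 2366 with array weights, 1366 in the 6 arrays of that time and 0 with the replicate block within each time (limma, 751 genes at an unadjusted p under 0.05 in the fit of 12 arrays). On the 12 h arrays alone the 1366 genes became 506 with no filter, 904 without the probe set types that can cross-hybridise, 2351 with the replicate block and 89 with a 2-fold minimum. At 48 h the 1262 genes became 327 with no filter, 3014 after quantile normalization, 2863 after centring, 5207 with array weights and 675 with a 2-fold minimum. The weights were very uneven at 48 h. Control replicate 2 had 5.09 against 0.41 and 0.29, and Ra replicate 3 had 2.22 against 0.37 and 0.05. Weighted counts that use the 48 h arrays therefore rest largely on 1 array per group. They became 0 in the 6 arrays of that time (limma, 1748 at an unadjusted p under 0.05), and 0 when Ra 48 h replicate 2 was also left out. The 2 genes whose effect differed between the times became 5 with no filter, 43 with a stricter filter, 944 after quantile normalization, and 856 after centring. They became 17 with robust variance, 4464 with array weights, 60 with the replicate block and 36 with the block within each time. The stricter filter removed C5AR1 and CLIP4, so neither was among the 43. For the control cells over time the 1955 genes became 1253 with no filter, 3709 after quantile normalization, 3555 after centring, 6127 with array weights, 1019 with a 2-fold minimum and 3334 in the 6 control arrays. The count of 1 gene called at both times in the same direction became 0 with no filter, 43 after quantile normalization, 37 after centring, 732 with array weights, 0 with the block within each time and 141 with 12 h calls from 6 arrays. Lists called at 48 h and for the difference, 12 and 15, became 7 and 8 without the probe set types that can cross-hybridise. With an estimated correlation camera called 0 lists at 12 h, 0 at 48 h and 0 for the difference, and fry called 0, 0 and 0, against 12, 12 and 15 with the preset correlation (1, 1 and 0 lists at an unadjusted p under 0.05 with an estimated correlation). Leaving out each array in turn gave 0 to 219 genes at 12 h, 293 to 1388 on the 12 h arrays alone, 45 to 2725 at 48 h, 1 to 1041 for the difference, 788 to 4095 for the control cells, and 0 to 45 at both times. Lists numbered 8 to 16, 9 to 12 and 10 to 17 at 12 h, at 48 h and for the difference. The median of the TGF-beta list at 48 h reversed from 0.19 to -0.016 without Ra 48 h replicate 3, and reached 0.382 without Ra 48 h replicate 2. Over all alternatives, the 40 genes named and called at 48 h kept direction and call in 727 instances and lost the call with the direction kept in 266. The same counts were 35 and 37 for the 3 genes called at 12 h and 287 and 22 for the 20 genes named from the 12 h arrays alone. They were 36 and 8 for the 2 genes of the difference, and 509 and 113 for the 24 list calls. A gene or list that a setting removed was not counted there. The stricter filter kept 38 of the 40 genes and 14 of the 20, and it removed the 2 genes of the difference. Low signal limits genes under 5 log2 units, where GCRMA's background model sets the fold change.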

Other observations

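The FOXO list was chosen after the 12 h result was seen.

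Some lists with a bearing on kidney toxicity were not called at 12 h in the fit of 12 arrays. The p53 target genes had a median of 0.03 log2 units (camera adjusted p = 0.404) and genes of kidney injury 0.16 (0.0807). The list of endoplasmic reticulum chaperones and the unfolded protein response had a median of 0.23 (camera adjusted p = 0.13). The ATF4 and amino acid response had 0.15 (0.218), DNA replication 0.08 (0.404) and cytosolic ribosomal proteins 0.01 (0.934). In the 6-array fit camera called the chaperone list, which was higher (adjusted p = 0.0057, 0.571 with an estimated correlation, fry 0.134), and 5 of its 23 genes rose. Of 26 p53 targets 4 rose and 2 fell in that fit, and that list was not called (adjusted p = 0.598). An adjusted p that misses the threshold does not show that these lists stayed the same.

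A hypothesis came from TXNIP, KLHL24, FBXO32 and CREBRF, known targets of FOXO transcription factors or linked to them, which were seen among the rises at 12 h. A list of 15 other FOXO targets was then written before their values were looked at, and 11 were measured. Their median at 12 h was 0.38 log2 units, at percentile 99.98 of 10000 random lists matched on expression (central 95% from -0.18 to 0.19), and 9 of 11 were positive. In the 6-array fit 4 rose, CCNG2 by 0.88, SOD2 by 0.51, RICTOR by 0.48 and CDKN1B by 0.40, and 0 fell. Camera gave an unadjusted p = 0.00130 with the preset correlation and p = 0.119 with an estimated correlation. At 48 h their median was -0.37, with CAT (-0.71) and EIF4EBP1 (-1.15) past the test, both lower. Higher FOXO activity at 12 h may be a candidate explanation, given the median of 0.38, but it was found and tested on the same samples.

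For the comparisons of 3 arrays with 3, the 10 splits of the samples are too few for a share under 0.05. The real split gave 3 genes at 12 h (highest other 0), 1366 on the 12 h arrays alone (0), 1262 at 48 h (158) and 1955 for the control cells (0), each as the 1 split with a count as large. At 12 h, where the numbers may pair the samples, 4 of the 10 splits part all pairs, and the highest other count was 0 among them and 0 among the rest. For lists, 5 of 10 splits gave as many as the real 12 at 12 h (highest other 14) and 5 of 10 as many as the real 12 at 48 h (15). For the 1 gene called at both times in the same direction, 2 of 100 splits gave as many (highest other 1), a share under 0.05, and both were among the 44 drawn splits that part the pairs of 12 h (0 of the other 56). With the replicate block within each time the count was 0, so a single gene carries little weight here. It also became 0 without any 1 of the 12 h arrays, Ra 48 h replicate 3, control 48 h replicate 1 or control 48 h replicate 2, and 45 without Ra 48 h replicate 2.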
